A study of Homo sapiens with 4 samples.

How the data were processed

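RNA from LNCaP cells was measured in 4 samples, 3 transfected with REST siRNA and 1 with control siRNA, all harvested 3 days after transfection. Each sample was labelled with Cy3 and hybridized to a one-colour Agilent array. All 4 arrays were on 1 slide with the same scan, so no slide or scan batch could be separated. Groups were taken from the sample labels. The labels number the REST siRNA samples 1 to 3 and do not state whether they are different siRNA sequences or separate cultures.

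The deposited scanner files hold spot intensity on a linear scale. Per the file headers they were made by Agilent Feature Extraction 11.0.1.1 with a one-colour gene expression protocol on a grid of 384 rows and 164 columns, and the array design refers to genome build hg19. The submitters' processing notes name Feature Extraction 9.1. Which of these versions made the values stays open. Per the file headers the processed signal had its background subtracted and spatial trends removed, and it was not normalized between arrays. The deposited series value table holds log2 values. From the values, its 4 columns share a single distribution (median 6.4141 in each), as quantile normalization gives, and each column correlated best with log2 of its own array's processed signal (0.9995 to 0.9999, against at most 0.9886 with any other array). Its scale and direction were thus settled from the values, and it was not centred per gene. How it was made is otherwise not given in the sources used here, and it served only as an alternative.

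The processed signal was taken as log2 minus each array's 75th percentile, which was 854.6, 861.3 and 808.4 on REST siRNA arrays 1 to 3 and 790.3 on the control array. Control spots and spots flagged as outliers (311 to 427 per array) were left out. No spot was saturated (0 on each array). Spots of a probe were averaged. A probe counted as well above background on an array where at least 50% of its spots were. Of 42405 probes other than controls, 86 were lost to flags and 26279 were kept because they were well above background on all 3 REST siRNA arrays or on the control array. Accessions in the files were matched without versions to a RefSeq gene table of assembly GRCh38.p14, used for names only. It named 26364 probes, or 19796 symbols, and other probes kept their accession. Because the table's assembly is not that of the arrays, no coordinates are given. For the 3870 names with several probes, the brightest probe by mean over all 4 arrays stood for the gene. This left 21461 genes, 13992 of them with a symbol.

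REST siRNA was compared with control siRNA by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The fit had 2 residual degrees of freedom, all from the REST siRNA arrays, and a prior of 2.09. The single control array was assumed to vary like the others, and the number of arrays limits the precision. Where a gene was not well above background on any array of a group, its fold is given as a lower bound. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the dim probe's own value and the lowest signal among probes well above background. It is a point value that makes no allowance for the spread between arrays, so the fit's 95% limit can lie below it. It holds for the background-subtracted signal and is smaller with normexp, whose offset compresses dim signals. Counts of genes at least 2-fold from control on every REST siRNA array carry no test.

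The 19 gene lists were fixed before the data were examined, as were the tests of genes and of lists, the rule for named genes and all alternatives except the 2 named as added. Most tests in the closing section were chosen later, as stated there. Lists were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists, and their medians were set against 10000 random lists matched on brightness. Camera with an estimated correlation and fry were alternatives. Camera with an estimated correlation is held to the 2 residual degrees of freedom of the fit, so it could hardly call a list here. Its adjusted p of 0.80 is shared by most lists, because the adjustment ties them. By the rule, the text names REST, the 12 largest rises and 12 largest falls among genes with a symbol that passed, moved the same way on all 3 arrays and were well above background in both groups. It adds up to 3 bounded genes per direction and up to 4 members per list with the largest differences. Further genes in the text (NEFL, SCN3A, ST18, POU3F4 and those introduced so in the closing section) were chosen after their values were seen.

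The fit was tested on simulated data for REST siRNA against control siRNA, with 21461 genes and 50 changed genes per size. It called 30% of genes changed by a log2 of 1, 92% at 2, 94% at 3 and 96% at 4, with 8 calls among unchanged genes. With no gene changed it made 0 calls. The simulated control array had the same noise as the others, so these figures do not test that assumption. They do not cover false calls from signal found on the control array alone.

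The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of each array, no filter on dim probes, probes well above background on all 4 arrays, the mean of a gene's probes, the series value table, an intensity trend with robust variance, and each REST siRNA array left out in turn. Normexp was planned on the mean spot signal. The files used here hold the median spot signal, and that deposited intensity and the median local background were used in its place. A pair of settings was added after the data were seen, without probes that have a spot on the upper 50% of grid rows, and with probes well above background on all 3 REST siRNA arrays. Tables and plots used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.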

Results

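Gene expression was measured on 4 one-colour Agilent arrays of LNCaP cells, an androgen-sensitive human prostate cancer line. The cells were transfected with small interfering RNA (siRNA) and harvested 3 days later. On 3 arrays the siRNA was directed against REST, a zinc-finger repressor that keeps neuronal genes silent outside the nervous system, and 1 array held cells given control siRNA. The labels number the REST siRNA arrays 1 to 3 and do not say whether these are different siRNA sequences or repeats of the same one. Between 60.5% and 65.0% of probes were well above background on each REST siRNA array, and 61.1% on the control array. The REST siRNA arrays correlated with each other at 0.993 to 0.994 over 21461 genes and with the control array at 0.979 to 0.980. All values below are log2 differences, REST siRNA minus control siRNA, with the standard error of the limma fit (3 arrays against 1). The control group had no replicate, so its array was assumed to vary like the REST siRNA arrays. The limma p-values rest on the spread between the 3 REST siRNA arrays, moderated across genes, and that spread may be technical. The list p-values of camera with a preset correlation compare genes with each other. Neither kind measures how control cultures vary.

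REST itself was lower on every REST siRNA array. Its signal was 23.6%, 26.2% and 30.1% of control on arrays 1, 2 and 3, and the mean log2 difference was -1.92 ± 0.16 (limma adjusted p = 0.032). A single probe measured REST. The call was lost without array 1 (-1.83, adjusted p = 0.082), without array 2 (-1.91, adjusted p = 0.13), without the filter on dim probes (-1.92, adjusted p = 0.18) and when probes had to be well above background on all 4 arrays (adjusted p = 0.055).

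The first question was whether genes that REST is known to repress responded to its depletion. Of 63 neuronal genes listed as REST targets before the data were examined, 39 were measured. Their median log2 difference was 2.04, a 4.10-fold higher level after REST siRNA. It stayed at 2.04 with genes dim on control at their lower bound. The median is the value of MAPK8IP2, which the control array measured, so these bounds could hardly move it. The rise itself helped some genes past the filter, and 8 of the 39 were dim on control. The median was 0.38 over all 63 members with dim probes kept and 0.86 over the 31 members well above background on all 4 arrays. It was 0.94 with normexp and 0.98 over the 12 members left without the upper 50% of grid rows. Of the 39, 10 rose, none fell and 29 did not pass limma's test over all genes. Adjusted over the list alone, 26 rose and none fell. On all 3 REST siRNA arrays 32 of the 39 lay above control, and 22 lay at least 2-fold above it. The synaptic vesicle protein SYP rose at least 39.9-fold (limma adjusted p = 0.010) and the vesicle-priming factor UNC13A at least 30.2-fold (adjusted p = 0.028). Both were not well above background on the control array, so their folds follow the rule for lower bounds. For UNC13A that bound equals the fitted log2 difference of 4.92, and for SYP it is 5.32 against a fitted 5.33. CHRNB2, a subunit of neuronal nicotinic acetylcholine receptors, rose by 5.04 ± 0.55 (adjusted p = 0.0498). Chromogranin A, encoded by CHGA, was at least 130-fold above control, but its level varied between the REST siRNA arrays (0.66, 0.94 and -1.06 in log2 relative to each array's 75th percentile) and it did not pass (adjusted p = 0.065). These bounds hold for the background-subtracted signal and make no allowance for the spread between arrays. The fit's lower 95% limits were log2 differences of 4.79 for SYP, 3.85 for UNC13A and 4.66 for CHGA. With normexp, whose offset compresses dim signals, the log2 differences were 2.10 for SYP, 1.86 for UNC13A, 3.20 for CHRNB2 and 3.49 for CHGA, and CHGA then passed (adjusted p = 0.035).

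Not every listed target moved. NEFL, a neurofilament subunit, stood at -0.41 ± 0.17 and SCN3A, a sodium channel, at -0.12 ± 0.15. The middle 50% of the list ran from 0.29 to 3.19. As a list, the targets were called higher by limma's camera test (adjusted p = 1.94e-15 over 19 lists, with a preset correlation of 0.01). The call was lost with a correlation estimated from these arrays (camera p = 0.092 unadjusted and 0.80 adjusted, with an estimated correlation). With 2 residual degrees of freedom that test could hardly call any list, so this loss decides little. The list's median lay at percentile 100 of 10000 random lists of like brightness.

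**Figure D1:**
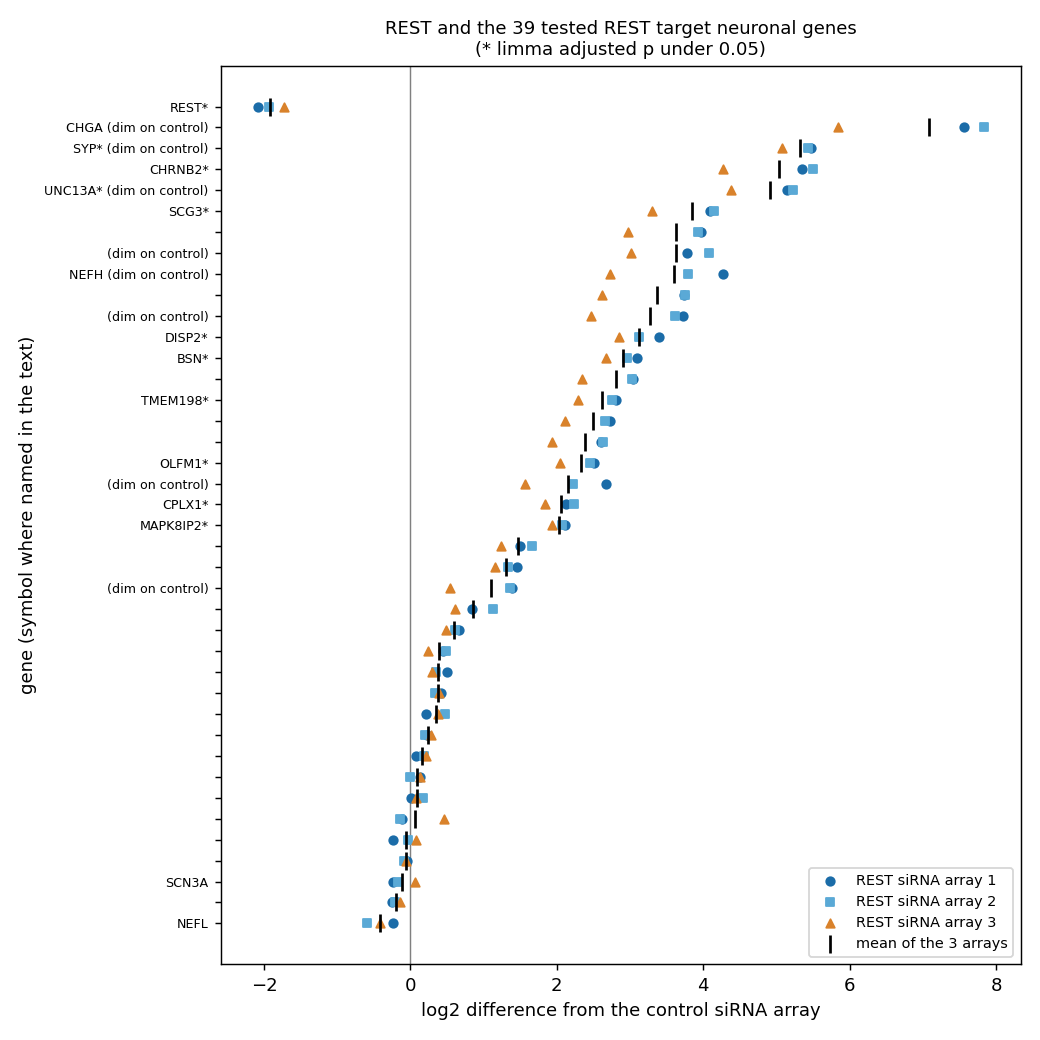
REST and the 39 tested REST target neuronal genes, with the log2 difference of each REST siRNA array from the control siRNA array on the horizontal axis. Points are the 3 arrays, bars are their means, and an asterisk marks a limma adjusted p under 0.05; genes named in the text carry their symbol, and values of genes dim on control are not exact. REST lies near -1.92, while 32 of the 39 targets lie above 0 on all 3 arrays.

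Across the transcriptome, 69 genes rose and 230 fell (limma, Benjamini-Hochberg adjusted p under 0.05, 21461 genes), of which 53 and 97 had a gene symbol. Of the 69 rises, 10 were in listed REST targets. Among genes well above background in both groups, the steepest rises after CHRNB2 were in SCG3, a secretory granule protein (3.85 ± 0.39, limma adjusted p = 0.043), and STMN3, a neuronal microtubule regulator of the stathmin family (3.57 ± 0.17, adjusted p = 0.015). GNG4, a G protein gamma subunit, rose by 3.13 ± 0.12 (limma adjusted p = 0.010). The membrane protein genes DISP2 and TMEM121B rose by 3.12 ± 0.23 and 2.91 ± 0.29, and BSN, a scaffold of the presynaptic active zone, by 2.91 ± 0.19. TMEM198, NKAIN1 and OLFM1 rose by 2.62 ± 0.24, 2.56 ± 0.26 and 2.33 ± 0.22. CPLX1, which acts in vesicle fusion, rose by 2.06 ± 0.18, and MAPK8IP2, a scaffold of the JNK pathway, by 2.04 ± 0.11. Of the genes dim on the control array, the potassium channel KCNH6 rose at least 48.9-fold (limma adjusted p = 0.019) and LRTM2 at least 31.5-fold (adjusted p = 0.024). For KCNH6 the bound equals the fitted log2 difference of 5.61. The fit's lower 95% limits for KCNH6 and LRTM2 were log2 differences of 4.70 and 4.15. With normexp their log2 differences were 2.20 and 1.81, and those of the measured rises from SCG3 to MAPK8IP2 lay between 1.05 (OLFM1) and 2.96 (STMN3).

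The falls were smaller where both groups gave a measurable signal. Of the 230 genes that fell, 40 were well above background on all 4 arrays, 17 of them with a symbol. TPTEP1, a pseudogene transcript, fell by 1.56 ± 0.11 on the log2 scale (limma adjusted p = 0.025). SLC5A2, a sodium-glucose transporter, changed by -1.34 ± 0.09, and LCA5, a protein of the cilium, by -1.34 ± 0.14. HECTD2-AS1, an antisense RNA, changed by -1.22 ± 0.08. ZNF750, a transcription factor of epithelial differentiation, and MPZL2, an adhesion protein, changed by -1.19 ± 0.10 and -1.17 ± 0.09. The remaining named falls were MPP7 (-1.02 ± 0.10), GBA3 (-0.96 ± 0.10), CTSO (-0.92 ± 0.09), ZDHHC2 (-0.89 ± 0.09), JRKL (-0.87 ± 0.08) and RAB6D (-0.83 ± 0.09). Their limma adjusted p-values lay between 0.024 and 0.047. Second probes gave -0.62 for MPZL2 and -0.18 for JRKL, and RAB6D belongs to a family of near-identical copies, so these 3 are uncertain. HECTD2-AS1 is uncertain too. Of 33 other tested genes within 5 rows and columns of its spot, 6 were at least 2-fold lower on every REST siRNA array. For each of the other named falls this count was 0 or 1. MPP7, GBA3, CTSO, ZDHHC2, JRKL and RAB6D did not reach that 2-fold limit on every array themselves. The count thus cannot clear these genes of local signal of their own size.

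The other falls came mostly from probes that only the control array measured: 176 of the 230 were not well above background on any REST siRNA array, and 14 on some. The filter admits such falls, since it kept probes bright on the control array alone but otherwise required all 3 REST siRNA arrays. The widest were TEX50 (at least 2508-fold lower, limma adjusted p = 0.0065), FOXB2 (at least 30.0-fold, adjusted p = 0.0075) and PSG5 (at least 25.2-fold, adjusted p = 0.018). With normexp their log2 differences were -8.41, -1.95 and -1.99. Of these 176 genes, 84.7% lay on the upper 50% of the rows of the array grid, which held 50.4% of the genes tested. Of the 40 falls measured on all arrays, 67.5% did so (exact 95% interval 50.9% to 81.4%), and of the 69 rises 47.8% (35.6% to 60.2%). The control array had 36 spots with a background signal over 100, against 0 on each REST siRNA array, and 107 nonuniform spots, against 27, 13 and 3. When probes had to be well above background on all 4 arrays, as planned before the data were seen, limma called 6 genes higher and 1 lower of 19835 (2125 and 2718 at an unadjusted p under 0.05). Of the rises and falls named above, only STMN3, GNG4 and MAPK8IP2 passed there. When they had to be so on all 3 REST siRNA arrays, a setting chosen after the data were seen, 57 genes rose and 27 fell.

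The counts of calls rested on few arrays. Without array 1, and likewise without array 2, limma called no gene in either direction, although 1493 genes were higher and 2018 lower at an unadjusted p under 0.05 without array 1, and 1507 and 2220 without array 2. Without array 3, 95 rose and 246 fell. Counts that need no spread estimate gave 114 genes at least 2-fold higher than control on every REST siRNA array and 435 at least 2-fold lower. When each REST siRNA array in turn was set against the other 3 arrays, 3 to 46 genes were at least 2-fold higher on all of the others and 206 to 373 at least 2-fold lower. Among genes well above background on all 4 arrays, 61 were higher and 48 lower than control on every REST siRNA array. The same limit gave 0 to 6 higher and 18 to 36 lower with each REST siRNA array set alone.

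**Figure D2:**
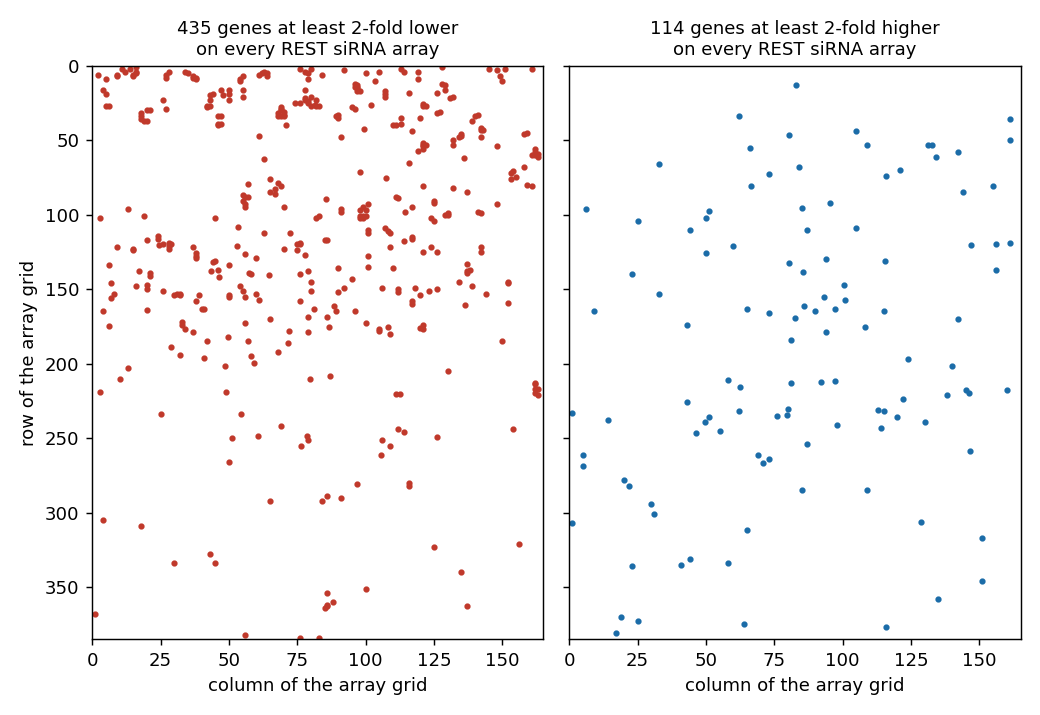
Grid position (column and row of the array) of the 114 genes at least 2-fold higher and the 435 genes at least 2-fold lower on every REST siRNA array, each point 1 gene at its probe's median row and column. Rows 1 to 48 hold 153 of the lower genes and 5 of the higher genes.

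Cell cycle genes were higher together, by a smaller amount. The median of 39 tested members was 0.59, or 1.51-fold, and 32 of them lay above control on all 3 REST siRNA arrays. PLK1, a kinase of mitotic entry, rose by 1.46 ± 0.14 (limma adjusted p = 0.036). It was the 1 member past the test over all genes, and a second probe gave 0.97. Adjusted over the list alone, 13 rose and none fell. The mitotic transcription factor FOXM1 stood at 0.96 ± 0.19, the phosphatase CDC25C at 0.92 ± 0.18 and the kinase AURKA at 0.91 ± 0.14, none of them past the test. The list was called higher by camera (adjusted p = 2.97e-09, with a preset correlation of 0.01). The correlation of its members estimated from these arrays was 0.93, so the preset treats them as far more independent than this estimate does. The call was lost with the estimate (camera p = 0.34 unadjusted and 0.80 adjusted, with an estimated correlation).

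Neuroendocrine prostate cancer markers shared members such as SYP and CHGA with the REST target list, and were higher by a smaller median. Of 15 tested markers, 3 rose (SYP, CHRNB2 and SCG3), none fell and 12 did not pass. These 3, and all 5 markers at least 2-fold higher on every REST siRNA array, were also on the REST target list. The large rises in this list are thus not separate from those of the REST targets. Adjusted over the list alone, 7 rose and 2 fell. The 2, ST18 and POU3F4, were well above background on the control array but on 0 and 1 of the REST siRNA arrays. The median was 0.47 (camera adjusted p = 0.041; adjusted p = 0.80 with an estimated correlation). The median turned to -0.043 when dim probes were kept. The call also ended without array 1 (adjusted p = 0.060), with probes well above background on all 4 arrays (adjusted p = 0.11) and without probes on the upper 50% of grid rows (adjusted p = 0.43).

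Genes of androgen signalling showed no call. Of 37 tested androgen-induced genes none passed, over all genes or adjusted over the list alone, and their median was -0.07 (camera adjusted p = 0.78). The largest differences were MAF at -0.60 ± 0.12, AZGP1 at 0.60 ± 0.17, HPGD at 0.57 ± 0.46 and NDRG1 at 0.54 ± 0.23. The direction of this small median turned under quantile normalization (0.0057) and in the series value table (0.0095). The median of 15 androgen-repressed genes was -0.19 (camera adjusted p = 0.38), with CCN3 at -0.74 ± 0.21, ID3 at 0.68 ± 0.14, ID1 at 0.66 ± 0.22 and AMIGO2 at -0.65 ± 0.09. None of these passed the test over all genes. Adjusted over the list alone, 2 of the 15 rose and 3 fell.

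Stress and signalling lists were not called in the main setting either. The median of 20 p53 target genes was 0.17 (camera adjusted p = 0.068), with CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, at 0.86 ± 0.16 and ZMAT3 at 0.46 ± 0.10. Hypoxia-induced genes had a median of 0.19 over 20 members (camera adjusted p = 0.069), with ALDOC at 0.61 ± 0.17 and ENO2 at 0.47 ± 0.12. Both lists were called in 7 of 13 alternative settings, but not with an estimated correlation (adjusted p = 0.80 with an estimated correlation for both). Endoplasmic reticulum and amino acid stress genes had a median of 0.11 over 21 members (adjusted p = 0.17), with CHAC1 at 0.58 ± 0.14. They were called in 3 of 13 alternatives (lowest adjusted p = 0.011), but not with an estimated correlation (adjusted p = 0.80 with an estimated correlation). Interferon response genes had 0.09 over 20 members (adjusted p = 0.38), with IFI44 at -0.77 ± 0.14. Autophagy genes had 0.02 over 28 members (adjusted p = 0.94; -0.0081 when arrays were scaled to their medians), with TFEB at -0.59 ± 0.12 and ULK2 at -0.44 ± 0.08. A second TFEB probe of like brightness gave 0.19, so the direction of TFEB is not settled. Their mean was -0.04, so median and mean differed in sign. Sterol and fatty acid synthesis genes had 0.10 over 26 members (adjusted p = 0.28), with INSIG1 at -0.51 ± 0.12. They were called in 1 of 13 alternatives (adjusted p = 0.021), but not with an estimated correlation (adjusted p = 0.87 with an estimated correlation). No member of these 6 lists passed over all genes or adjusted over the list alone.

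Lineage lists gave small medians. Epithelial junction genes had a median of 0.08 over 19 members (camera adjusted p = 0.52), with KRT19 at 0.86 ± 0.13, and adjusted over the list alone 1 member rose. Mesenchymal genes had 0.07 over 12 (adjusted p = 0.38), with VIM at -0.77 ± 0.31. Stemness genes had -0.03 over 7 (adjusted p = 0.52), with CD44 at -0.39 ± 0.19 and MYC at -0.35 ± 0.08. Genes of the REST corepressor complexes had -0.05 over 23 (adjusted p = 0.38), with RCOR2 at -0.47 ± 0.17, RCOR1 at -0.40 ± 0.09 and KDM1A at 0.37 ± 0.10. Reference genes had -0.05 over 15 (adjusted p = 0.81; 0.065 under quantile normalization and 0.075 in the series value table), with PGK1 at 0.42 ± 0.17 and GUSB at -0.27 ± 0.08. Except for KRT19's list, no member of these lists passed over all genes or adjusted over the list alone.

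Markers of other cell types were mostly below the filter. The median of 4 basal epithelial markers was -0.16 (camera adjusted p = 0.52), with ITGB4 at -0.44 ± 0.11, and that of 5 leukocyte markers 0.18 (adjusted p = 0.17), with CD3E at 0.23 ± 0.14. The leukocyte list was called in 1 of 13 alternatives (adjusted p = 0.0498; adjusted p = 0.80 with an estimated correlation in the main setting). The median of 4 stromal markers was -1.41 (adjusted p = 0.32), and 1 of them fell over all genes (2 adjusted over the list alone). PDGFRB was at least 4.60-fold lower (limma adjusted p = 0.044) and COL6A3 stood at -2.73 ± 0.69. PDGFRB was not well above background on any REST siRNA array, and COL6A3 was on 1. With PDGFRB at its bound the median was -1.14, and with probes well above background on all 4 arrays it was 0.060.

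**Figure D3:**
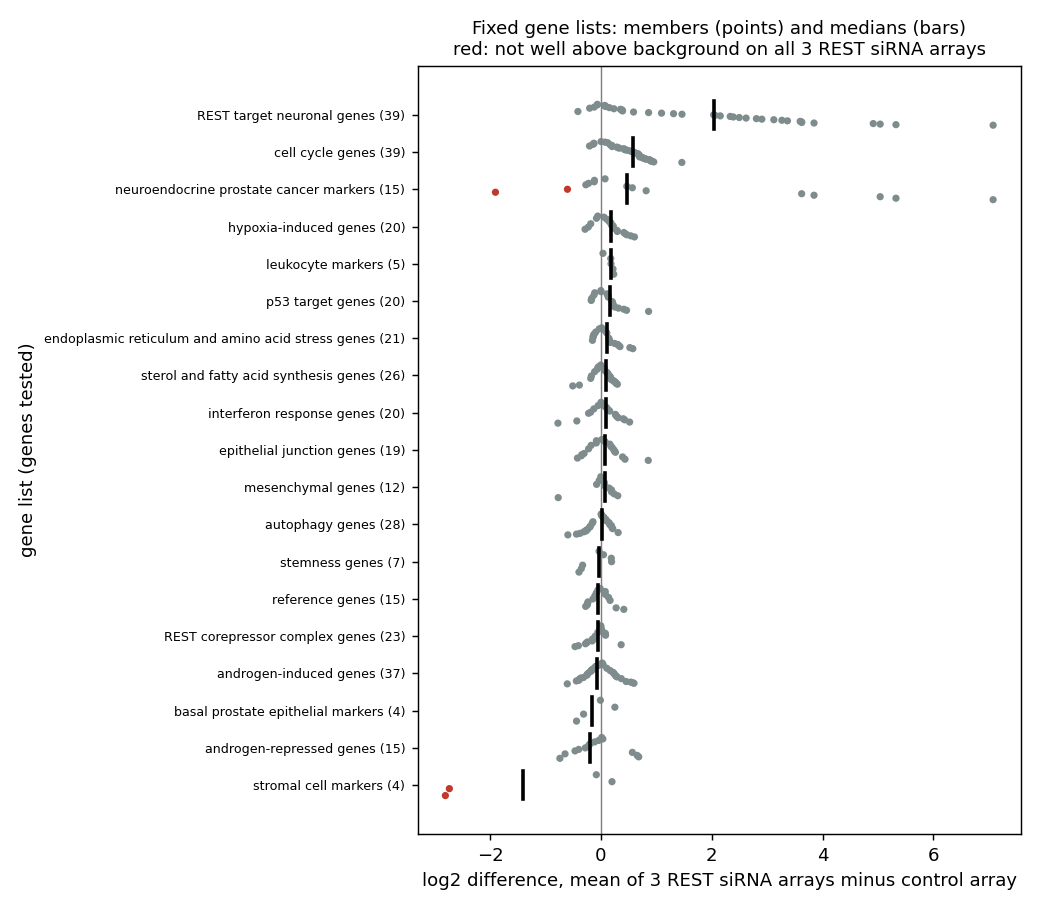
The 19 gene lists fixed before the data were examined, with the log2 difference (mean of 3 REST siRNA arrays minus the control array) of each tested member as a point and the list median as a bar. Red points are genes not well above background on all 3 REST siRNA arrays. The REST target list has its median at 2.04 and the cell cycle list at 0.59.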

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

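The settings without probes on the upper 50% of grid rows and with probes well above background on all 3 REST siRNA arrays were chosen after the data were seen. REST stayed lower in 12 of 12 alternatives (-2.01 to -1.24) and past the threshold in 8 (adjusted p from 0.0029 to 0.18). The REST target and cell cycle lists were called higher by camera in 13 of 13 (medians 0.38 to 2.10 and 0.51 to 0.69), always with the preset correlation. With an estimated correlation, 0.24 for the REST targets and 0.93 for the cell cycle genes, neither list was called (camera adjusted p = 0.80 for each). Fry called neither list. Its p was 0.0078 unadjusted and 0.061 adjusted for the REST targets, and 0.13 and 0.35 for the cell cycle genes. Camera with an estimated correlation has only 2 degrees of freedom here and thus little power. Signal over background limits the falls, since most rest on probes dim on the REST siRNA arrays. Except where the number of genes or arrays is named, the cause of each change below was not tested.

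With normexp, whose offset compresses dim signals, limma called 257 genes higher and 891 lower, 39 and 114 genes were at least 2-fold higher and lower on every array, and 7 lists were called. Medians turned for interferon (-0.0095), mesenchymal (-0.063) and leukocyte (-0.020) genes, as did RSAD2 (-0.024), SPARC (-0.055), DST (-0.046), CD3E (-0.023) and CD68 (-0.054). Quantile normalization called 6 lists and turned androgen-induced (0.0057) and reference genes (0.065). The series value table called 6 and turned the same lists (0.0095 and 0.075). Scaling to array medians turned autophagy genes (-0.0081). The mean of a gene's probes called 5 lists and turned reference genes (0.0081) and TWIST1 (-0.053). The robust trend called 623 genes higher, 1266 lower and 5 lists. Camera with an estimated correlation called 0 lists and fry 0.

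Without the filter 34369 genes were tested and limma called 0 higher and 0 lower (1758 and 2328 at an unadjusted p under 0.05). There, 305 genes were at least 2-fold higher and 632 lower, 5 lists were called, REST stood at -1.92 (adjusted p = 0.18), and neuroendocrine (-0.043) and basal (0.076) medians turned. With probes well above background on all 4 arrays limma called 6 higher and 1 lower, 61 and 48 genes passed 2-fold, REST stood at -1.92 (adjusted p = 0.055) and the stromal median was 0.060. With all 3 REST siRNA arrays required, 27 genes fell, 48 were at least 2-fold lower and the stromal median was 0.060. Without the upper rows, 10283 genes were tested, 30 rose and 31 fell, 55 and 52 passed 2-fold, and medians turned for interferon (-0.17), mesenchymal (-0.0062), stemness (0.12) and basal (0.12) genes. Of those calls, 27 and 30 were also called with all probes.

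Leaving out 1 REST siRNA array, which leaves 1 residual degree of freedom, gave 0 to 95 genes higher, 0 to 246 lower and 141 to 200 at least 2-fold higher (483 to 501 lower), with REST between -2.01 and -1.83 (adjusted p = 0.082 without array 1 and 0.13 without array 2). TWIST1 ran from -0.016 (without array 1) to 0.47, KRT15 from -0.038 to 0.051 (without array 1) and the stemness median from -0.061 to 0.028 (without array 2). No paired analysis was possible because the control group has a single array.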

Other observations

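The limma tests and the list's percentile among random lists were planned, and the comparison of other probes of the falling genes and that of array 3 with random lists were chosen before their results were seen; the other tests in this part, and the use of the percentile against scaling, were chosen after. Genes named here for the first time were chosen after their values were seen.

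Genes outside the fixed lists also rose. STX1A, a syntaxin of the vesicle fusion machinery, rose 2.82-fold (limma adjusted p = 0.039). The secretoglobins SCGB1D2 and SCGB1D1, small secreted proteins of glandular epithelia, rose by 1.76 ± 0.10 and 1.64 ± 0.09 (limma adjusted p = 0.018 for both). They are paralogs, and cross-hybridization between them was not tested. The hormone gene FGF21 rose by 1.96 ± 0.18 (limma adjusted p = 0.036) and CRIP2, a LIM-domain protein gene, by 1.97 ± 0.11 (limma adjusted p = 0.018). Neurofilament genes differed in value, with NEFH at least 12.1-fold above control (limma adjusted p = 0.11) and NEFL at -0.41 ± 0.17 (limma adjusted p = 0.24), so neither passed.

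KLK3, which encodes prostate-specific antigen, stood at -0.10 ± 0.09 (limma adjusted p = 0.51). It lay below control on all 3 REST siRNA arrays and did not pass.

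The first pattern is the 176 falls from probes that only the control array measured. Loss of the transcripts after REST siRNA is argued against for the 17 of these genes whose probe has several spots. On the control array the spots of 1 probe differed by a median of 3.34 log2 units over these 17, against 0.23 over 20 rises (two-sided permutation p = 1e-04). The median was 0.099 over the 14 of these rises that the control array measured (p = 0.002, two-sided permutation test). The filter passed a probe with 50% of its spots bright, which favours such disagreement among the falls. Falls from probes with a single spot are not covered. Other probes of 22 of the genes had a median of -0.04 (95% bootstrap interval -0.15 to 0.07), but all 27 of these probes were dim on the control array and could not show a fall there. Where other probes gave a signal they did follow: for 11 rises measured on control, 10 of 11 other probes were well above background on all REST siRNA arrays and their median was 0.90, against 0.13 for 4 rises dim on control (interval -0.15 to 1.80). Local signal on parts of the control array may account for many of these falls, since 84.7% lay on the upper 50% of grid rows (exact 95% interval 78.5% to 89.6%) against 50.4% of tested genes, and the control array alone had spots with a background signal over 100 (36, against 0 on each other array). A lone array gives such genes in any case under this filter. With each REST siRNA array set alone, 206 to 373 genes were at least 2-fold lower on all other arrays, against 435 for the control array. Grid positions of the genes bright on a lone REST siRNA array were not examined. Crowding on the upper rows may thus not be particular to the control array. The 36 spots with a background signal over 100 were not matched to the positions of the falls.

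The next pattern is the higher level of cell cycle genes. Scaling of the arrays is argued against, since the list's median lay at percentile 100 of random lists of like brightness. The shift was uneven: 23 mitotic genes had a median of 0.70 and all 23 lay above control on every REST siRNA array, while 16 replication genes had a median of 0.19 and 9 did so. The difference of 0.51 (two-sided permutation p = 1e-05, the smallest 100000 permutations can give; genes are not independent) appeared on each array, at 0.63, 0.53 and 0.44. REST siRNA acting on mitotic genes and the growth state of the single control culture could each give it, and with 1 control array they cannot be told apart.

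The last pattern is that REST target genes were lowest on REST siRNA array 3 in 27 of 39 cases (23 of the 23 with a mean log2 difference of at least 1), but it is not particular to them, since 38 of 39 cell cycle genes and 14 of 20 p53 target genes were lowest there too. Lower signal on array 3 for genes of like brightness is argued against, since 0% of 10000 random lists reached the targets' count (median 13). Signal compression is argued against by the spike-in controls, whose levels on array 3 followed those on arrays 1 and 2 with a slope of 1.002 (95% interval 0.991 to 1.012) and deviations of -0.09 to 0.07 from that line. The 39 targets lay at a median of -0.39 from that line (95% bootstrap interval -0.63 to -0.18). With a slope so near 1 this value restates the pattern, and only the slope bears on compression. Weaker REST depletion may contribute, since REST was highest there (-1.73, against -2.08 and -1.93), but 3 arrays are too few to test the relation, and another difference of that culture or siRNA, which the cell cycle genes share, stays open.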
